A study of Mus musculus with 9 samples.

How the data were processed

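RNA of whole oviduct from CD1 female mice was measured on 9 Affymetrix gene arrays: 3 of immature females of day 21, 3 of mature females in estrus and 3 of mature females in diestrus. Per the labels' protocols, each sample was pooled tissue from 5 animals, no hormonal stimulation was given, and RNA was extracted with RNAzol. The p-values therefore measure the spread between pools, not between single animals. Per the submitters' processing notes, the authors deposited log2 values made by RMA in Affymetrix Expression Console, which corrects background, normalizes quantiles between arrays and summarises each probe set by median polish. The base of the logarithm is not written with the values, and their range and the medians of the arrays were checked and lie where log2 values of RMA lie. Versions of Expression Console and RMA are not given in the sources used here. The number of arrays limits the precision.

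All 28214 probe sets were kept. Gene symbols came from the platform's annotation table: 21640 probe sets had 1 symbol, 1321 had several and 5253 had none. The 21640 covered 19937 genes, and for the 954 genes with several such probe sets the one with the highest mean over the 9 arrays stood for the gene. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. Ovgp1 and C3, on the list of genes to be named in any case, had no probe set with 1 symbol and were not analysed here.

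The 3 groups were fitted together in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), with 6 residual and 3.60 prior degrees of freedom and a median residual SD of 0.0957. Contrasts were estrus minus immature, diestrus minus immature, diestrus minus estrus, and the mean of both mature stages minus immature. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

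Comparisons, tests, gene lists, alternatives and the rule for naming genes were written before the data were examined. The rule named, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among called probe sets with 1 symbol, no overlap between the arrays of the groups and a mean in the higher group above the median of all probe sets. Predicted gene models, receptors for smell and taste and small RNAs were left out of these. It also named up to 4 called members of each list by size and up to 2 members not called by level, and in any case Foxj1, Pax8, Esr1, Pgr, Ltf and Mki67. The text takes a part of the list members so named. Of 42 lists written from general knowledge of the tissue, 41 had at least 5 measured genes. Each was tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the 123 tests of the 3 pairwise comparisons. Lists for neighbouring tissues and the groups of immunoglobulin, haemoglobin and histone probe sets were written after values had been seen. Among the planned lists, those of immediate early, heat shock and circadian clock genes were meant to check handling and time of day. Differences in these between the groups were not tested apart from stage.

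Alternatives changed 1 choice at a time, except that the intensity trend and the robust prior were changed together: the replicate number as a block, a filter on low intensity, probe sets with 1 symbol only, quantile normalization again, median centring, cyclic loess, an intensity trend with a robust prior, array weights, only the arrays of the groups compared, a size of at least 2-fold, an adjusted p under 0.01, the mean of all probe sets of a gene, and each array left out. Leaving out the arrays with high ovarian or muscle and Hox values together was added after seeing the data. The method was tested on simulated data with the spread of these arrays. At 1.5-fold, 64 of 67 changed probe sets were called for estrus minus immature, 73 of 77 for diestrus minus immature and 53 of 61 for diestrus minus estrus. False calls numbered 11, 13 and 8 in these comparisons, over all simulated sizes together. At 4-fold all were called, and a list shifted by -0.3 was recovered with 0 other lists called. In these simulations the noise was drawn for each probe set and array on its own. Shifts shared by many genes of 1 array, which the real arrays can hold, were absent. The shares called, and the list result in particular, therefore need not hold for the real arrays.

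The comparisons with immature oviduct share the 3 immature arrays. The correlation and covariance of their differences were set beside 100 simulations in which unchanged groups shared the same controls. Other splits of the arrays were counted for each comparison: 10 for each pair of groups and 84 for mature against immature.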

Results

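The series measured RNA of the whole oviduct, the tube that carries eggs, sperm and early embryos between ovary and uterus, in CD1 female mice that had received no hormone treatment. Total RNA was hybridised to 9 Affymetrix arrays in 3 groups of 3: sexually immature females of day 21, mature females in estrus and mature females in diestrus. Estrus is the phase of mating and ovulation, and diestrus is the phase of the cycle in which corpora lutea secrete progesterone. Each array carried RNA of pooled tissue from 5 animals. The deposited values are log2 intensities of 28214 probe sets after robust multi-array averaging (RMA). Their medians lay between 8.85 and 8.90 on the 9 arrays, and their interquartile ranges between 2.15 (estrus 1) and 2.41 (immature 3). Arrays of the same group correlated at 0.992 to 0.996 across probe sets and arrays of different groups at 0.990 to 0.995. No pair of arrays held identical values. On the first principal component, with 24.2% of the variance, the immature arrays scored between -16.5 and -9.94, the estrus arrays between -6.23 and 2.65 and the diestrus arrays between 13.2 and 14.3. On the second, with 19.5%, estrus 1 scored 21.9 and the other 8 arrays between -13.4 (diestrus 3) and 6.39. On the third, with 16.5%, diestrus 3 scored -19.3 and the other 8 arrays between -5.32 and 11.4. With 3 arrays per group, the number of arrays limits the precision: the median standard error of a difference between groups was 0.08 on the log2 scale.

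Genes typical of neighbouring organs differed between arrays of the same group. The genes in this paragraph were chosen after their values were seen. Inha, which encodes the inhibin subunit made by ovarian granulosa cells, had a log2 value of 12.42 on immature 2, 10.94 on diestrus 2, 10.33 on diestrus 3 and between 9.13 and 9.88 on the other 6. Cyp17a1, an androgen-synthesis enzyme of ovarian theca cells, stood at 10.06 on immature 2 and 10.27 on diestrus 2, against 7.48 to 8.89 elsewhere. Cyp11a1, which starts steroid synthesis from cholesterol, stood at 10.27 on diestrus 2 and 9.21 on diestrus 3, against 7.55 to 8.34 elsewhere. Akr1c18, the progesterone-inactivating enzyme of the corpus luteum, reached 11.53 on diestrus 2 and at most 8.15 elsewhere. On diestrus 3, the smooth muscle genes Myh11 (12.33, against 11.03 to 11.42 elsewhere) and Des (11.88, against 10.75 to 11.18) and the posterior homeobox gene Hoxd10 (10.21, against at most 9.00) were the highest of the 9 arrays. The fat cell gene Retn stood at 10.76 on immature 1 and 10.28 on immature 2, against 8.79 to 9.38 elsewhere.

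**Figure D1:**
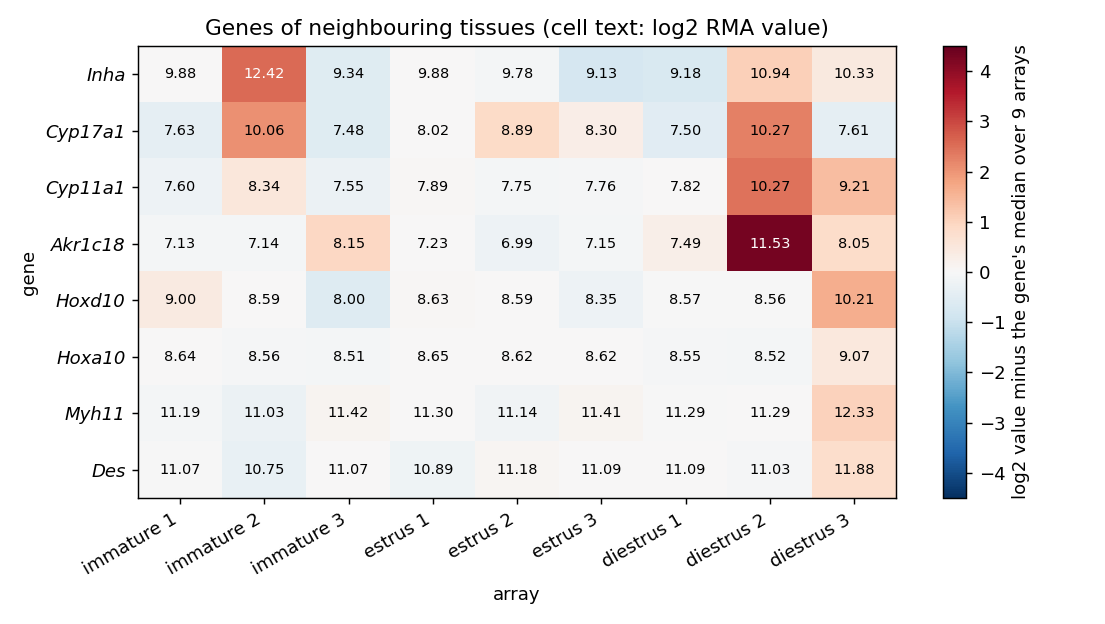
Log2 RMA values of 8 genes typical of ovary (Inha, Cyp17a1, Cyp11a1, Akr1c18), posterior reproductive tract (Hoxd10, Hoxa10) and smooth muscle (Myh11, Des) on each of the 9 arrays, with colour for the distance from the gene's median over the arrays. Each ovarian gene is highest on immature 2 or diestrus 2, and each muscle and homeobox gene on diestrus 3.

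The first comparison asked how the oviduct of cycling females in estrus differed from that of immature females. Jchain, the joining chain of secreted immunoglobulins A and M, showed the largest rise among the named genes: 9.05 ± 0.39 in estrus (SD, n = 3) against at most 7.30 on the 3 immature arrays (SD 0.27), 4.15-fold in intensity with a log2 difference of 2.05 ± 0.20 (SE; limma adjusted p = 0.0182). The immature values lay below the lower quartile of each array and were not shown to be above background, so the fold of the RNA itself was not determined. Mmd2 and the protocadherin gene Pcdh17 rose by 0.63 ± 0.08 and 0.54 ± 0.07 (adjusted p = 0.0369 for both). The immature values of Pcdh17 lay below the median of each array and were not shown to be above background. Ccna1, which encodes cyclin A1, fell by 1.03 ± 0.08, from 10.20 ± 0.15 to 9.16 ± 0.07 (SD, n = 3 each; limma adjusted p = 0.00618). Stil, needed for centriole duplication, fell by 0.75 ± 0.10 and Adam5 by 0.68 ± 0.09. Nrep and the membrane protein gene Itm2a fell by 0.65 ± 0.09 and 0.55 ± 0.07, with adjusted p between 0.0369 and 0.0374 for these last 4 genes. The estrus values of Stil and Adam5 lay below the median of each array and were not shown to be above background. As the rule for naming required, in each of the 8 genes the 3 arrays of one group lay apart from the 3 of the other, which chance gives for 10% of genes. Among genes examined whatever their result, the differences were 0.07 ± 0.05 for the estrogen receptor gene Esr1, 0.18 ± 0.11 for the progesterone receptor gene Pgr, 0.01 ± 0.10 for Pax8 of secretory cells, -0.10 ± 0.13 for Foxj1 of ciliated cells, 0.45 ± 0.18 for the estrogen-induced lactoferrin gene Ltf and -1.12 ± 0.24 for the division marker Mki67. None of these 6 passed the test (adjusted p = 0.203 for Mki67 and at least 0.695 for the others).

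Of 28214 probe sets, 9 were higher and 15 lower in estrus than in immature oviduct at an adjusted p under 0.05. They comprised 12 with 1 gene symbol, 8 with several and 4 without a name. At an unadjusted p under 0.05 there were 1839. The 24 calls became 7, 2 and 1 without immature 1, 2 and 3, then 7, 3 and 4 without estrus 1, 2 and 3, and 5, 5 and 95 without diestrus 1, 2 and 3, which add only to the estimate of spread. Of the 8 named genes, the numbers still called in the same 9 settings were 3, 1, 1, 2, 2, 2, 2, 2 and 8, with Ccna1 among them each time. Another normalization by cyclic loess left 1 higher and 4 lower, median centring gave 5 higher and 18 lower, and array weights gave 1023 calls.

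Among the gene lists fixed before the data were examined, those of cell division and of building cilia had lower values in estrus. All 39 measured proliferation genes had lower means than in immature oviduct, with a median log2 difference of -0.59 and none past the threshold over all probe sets, but 36 lower when adjusted over the list alone. Cdk1, the mitotic kinase, differed by -0.86 ± 0.21 and Pcna, the DNA polymerase clamp, by -0.14 ± 0.14 (adjusted p = 0.284 and 0.874). With a preset correlation of 0.01, limma's camera placed this list below other genes (adjusted p = 3.08e-45), and the call was lost with an estimated correlation (adjusted p = 0.204). In the program that builds multiple cilia, 19 of 20 genes had lower means, Stil passed the threshold and 8 were lower when adjusted over the list alone (median -0.16; camera adjusted p = 2.95e-09, and adjusted p = 0.204 with an estimated correlation), and the median was -0.10 without immature 3. Myb, a regulator of that program, differed by -0.17 ± 0.09. Imprinted and juvenile growth genes had a median of -0.23 with 12 of 23 lower over the list alone (camera adjusted p = 2.6e-09, and adjusted p = 0.202 with an estimated correlation). Midkine (Mdk) in this list differed by -0.57 ± 0.09 with an adjusted p of 0.0864. In cholesterol synthesis 19 of 20 genes had lower means, 1 passing over the list alone (median -0.20; camera adjusted p = 1.62e-08, and adjusted p = 0.339 with an estimated correlation). Squalene epoxidase, Sqle, differed by -0.35 ± 0.08 (adjusted p = 0.253). In the extracellular matrix list 29 of 32 genes had lower means and 2 were lower over the list alone (median -0.24; camera adjusted p = 1.87e-06, and adjusted p = 0.563 with an estimated correlation). Its member Sparc differed by -0.53 ± 0.14 (adjusted p = 0.318), and the abundant Dcn by 0.05 ± 0.07 (adjusted p = 0.894).

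Structural genes of motile cilia had lower means in 42 of 45 cases (median -0.12), none past the threshold or over the list alone. Their camera call (adjusted p = 3e-06, and adjusted p = 0.636 with an estimated correlation) ended without immature 3 (median -0.03, adjusted p = 0.402), and the median was -0.20 without immature 1 and -0.05 without estrus 3. The abundant Tppp3 differed by -0.15 ± 0.08. The ovarian list had a median of -0.13 (camera adjusted p = 0.0154, and adjusted p = 0.598 with an estimated correlation), which turned to 0.08 without immature 2, the array with the highest Inha, and its call also ended without estrus 2 (adjusted p = 0.0623). Without immature 1 that median was -0.23. Interferon response genes had lower means in 21 of 25 cases, none past the threshold and 2 over the list alone (median -0.12; camera adjusted p = 1.86e-05, and adjusted p = 0.281 with an estimated correlation). The immunoglobulin and B lineage list, with Jchain past the threshold and 2 of 11 genes higher over the list alone, had a median of 0.06 (camera adjusted p = 0.0237, and adjusted p = 0.446 with an estimated correlation). That median was 0.09, 0.10 and 0.04 without immature 1, 2 and 3 and 0.03 and 0.14 without estrus 1 and 2, and its call ended without immature 3 (adjusted p = 0.0515). For class II antigen presentation, H2-Aa differed by 0.56 ± 0.09 and Cd74 by 0.17 ± 0.15 (adjusted p = 0.0864 and 0.86). In all, camera with the preset correlation placed 8 lists above and 13 below other genes among 41 tested, and none with an estimated correlation. The fry test, which asks whether a list's genes move one way on balance, called 1 of the 41, the imprinted and juvenile growth genes (adjusted p = 0.0499), and gave 0.0598 for proliferation and 0.0621 for the multiciliogenesis program. The adjustment covered 123 tests, the 41 lists in 3 comparisons.

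The next comparison set diestrus against immature oviduct. Lipf, which encodes gastric lipase, rose 10.6-fold in intensity, from 8.73 ± 0.10 to 12.15 ± 0.28 (SD, n = 3 each), a log2 difference of 3.41 ± 0.26 (SE; limma adjusted p = 0.00183). The immature values of Lipf lay below the median of each array and were not shown to be above background, so the fold of the RNA itself was not determined. Jchain rose by 2.16 ± 0.20 (adjusted p = 0.00301). Inmt, a methyltransferase gene, rose by 1.44 ± 0.23, the kallikrein gene Klk1b11 by 1.09 ± 0.19, the aldehyde oxidase gene Aox3 by 0.99 ± 0.17, Wfdc18 by 0.98 ± 0.17, the metalloreductase gene Steap4 by 0.95 ± 0.13 and Gpnmb by 0.93 ± 0.17 (adjusted p between 0.0144 and 0.039). The immature values of Klk1b11 and Gpnmb, and of Ccl3, Iigp1 and Star named below, also lay below the median of each array. They were not shown to be above background. The falls included cell division and centriole genes. Stil fell by 1.16 ± 0.10, Ccna1 by 1.08 ± 0.08, Deup1, which organises the deuterosomes where centrioles of ciliated cells form, by 1.07 ± 0.13, and the polo-like kinase gene Plk4, which starts centriole duplication, by 1.04 ± 0.12. Ccna2 (cyclin A2) fell by 1.04 ± 0.17, Cdc20b by 1.01 ± 0.13 and Nt5dc2 by 1.02 ± 0.17. Lrat, the enzyme gene that esterifies retinol for storage, fell by 1.07 ± 0.14, with adjusted p between 0.00183 and 0.0324 for these 8 falls. The diestrus values of Stil, and of Racgap1 named below, lay below the median of each array and were not shown to be above background.

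In diestrus 83 probe sets were higher and 199 lower than in immature oviduct at an adjusted p under 0.05, of which 231 carried 1 gene symbol. Of the 282, 28 differed at least 2-fold, and 3776 probe sets had an unadjusted p under 0.05. The count became 58, 41 and 52 without immature 1, 2 and 3, then 154, 257 and 153 without estrus 1, 2 and 3, and 80, 45 and 533 without diestrus 1, 2 and 3. Of 41 named genes past the threshold, 7 were called whichever single array was left out: Lipf, Jchain, Stil, Ccna1, Plk4, Nsdhl and Fdft1. The number called was 11, 10 and 12 without immature 1, 2 and 3, then 24, 33 and 22 without estrus 1, 2 and 3, and 16, 9 and 36 without diestrus 1, 2 and 3. A fit of only these 6 arrays gave 85 calls, array weights gave 1288, and cyclic loess moved the split to 82 higher and 123 lower.

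Proliferation genes had lower means in diestrus in 38 of 39 cases, 4 passed the threshold and 34 over the list alone (median -0.49; camera adjusted p = 1.74e-23, and adjusted p = 0.341 with an estimated correlation). Besides Ccna2, the cytokinesis genes Ect2 and Racgap1 fell by 1.01 ± 0.14 and 0.66 ± 0.13, and Ccnb2 (cyclin B2) fell by 0.88 ± 0.17 (adjusted p between 0.0164 and 0.0496). Cdk1 and Mki67 both differed by -0.88, with SE of 0.21 and 0.24 and adjusted p of 0.0971 and 0.143. Mki67 stood at 9.63 on diestrus 3, the array with the highest muscle and homeobox values, and at 8.69 and 8.89 on the other diestrus arrays. All 20 genes of the multiciliogenesis program had lower means, 7 fell, among them Stil, Deup1, Plk4 and Cdc20b, and 12 were lower over the list alone (median -0.24; camera adjusted p = 2e-14, and adjusted p = 0.169 with an estimated correlation). The fry test gave an adjusted p of 0.0172 for this program and 0.0842 for proliferation. Foxj1, the regulator of motile cilia, differed by -0.23 ± 0.13 (adjusted p = 0.49). The 45 structural genes of cilia had a median of -0.11 with none past the threshold or over the list alone (camera adjusted p = 0.00286, and adjusted p = 0.71 with an estimated correlation). That call ended without immature 3 (adjusted p = 0.984) and without diestrus 3 (adjusted p = 0.126). Its median was -0.20 and -0.03 without immature 1 and 3 and -0.17 without diestrus 2.

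Cholesterol synthesis was lower as a group in diestrus. All 20 genes had lower means, 7 fell and 16 were lower over the list alone (median -0.42; camera adjusted p = 3.89e-15, and adjusted p = 0.204 with an estimated correlation; fry adjusted p = 0.0312). Msmo1 fell by 0.89 ± 0.15, Nsdhl by 0.82 ± 0.09, Fdft1, the squalene synthase gene, by 0.80 ± 0.08, and Fdps by 0.72 ± 0.13 (adjusted p between 0.00534 and 0.0391), while Hmgcs1 differed by -0.67 ± 0.14 (adjusted p = 0.0654). Of 22 heat shock and unfolded protein genes, 19 had lower means, 2 fell and 12 were lower over the list alone (median -0.26; camera adjusted p = 1.01e-07, and adjusted p = 0.359 with an estimated correlation). These 2 were the chaperone genes Hsph1 (fall of 0.64 ± 0.12, adjusted p = 0.047) and Hsp90aa1 (fall of 0.40 ± 0.07, adjusted p = 0.0342), while the abundant Hspa8 differed by -0.19 ± 0.06 (adjusted p = 0.172). Among 23 imprinted and juvenile growth genes 3 fell and 8 were lower over the list alone: Mest fell by 0.53 ± 0.10, Mdk by 0.52 ± 0.09 and Peg3 by 0.42 ± 0.07 (adjusted p between 0.039 and 0.0458). The values of Mest lay below the median of each array in both groups and were not shown to be above background. The list's median was -0.23 (camera adjusted p = 6.63e-05, and adjusted p = 0.294 with an estimated correlation) and -0.14 without diestrus 2.

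Of 19 secretory genes, 2 rose, Gpx3 (extracellular glutathione peroxidase) by 0.80 ± 0.12 and Clu (clusterin) by 0.64 ± 0.11 (adjusted p = 0.0221 and 0.0356), and 6 were higher over the list alone (median 0.07; camera adjusted p = 0.000249, and adjusted p = 0.16 with an estimated correlation). That median was 0.11 without immature 1 and 0.22 without diestrus 3. Lcn2 and Ltf, iron-binding defence proteins, differed by 0.71 ± 0.16 and 0.79 ± 0.18 (adjusted p = 0.0832 and 0.0837). Complement and antimicrobial genes had higher means in 28 of 31 cases, none past the threshold and 2 over the list alone (median 0.11; camera adjusted p = 6.98e-07, and adjusted p = 0.112 with an estimated correlation). For class II antigen presentation 8 of 9 means were higher. H2-Aa rose by 0.70 ± 0.09 (adjusted p = 0.013) and was also the 1 gene past the threshold over the list alone, and the list's median was 0.21 (camera adjusted p = 0.000414, and adjusted p = 0.16 with an estimated correlation) and 0.13 without immature 3. All 20 macrophage and dendritic cell markers had higher means, none past the threshold and 2 over the list alone (median 0.14; camera adjusted p = 9.78e-07, and adjusted p = 0.277 with an estimated correlation), and without immature 3 the median was 0.09. The chemokine gene Ccl3 rose by 0.36 ± 0.06 and the interferon-induced Iigp1 by 0.45 ± 0.09 (adjusted p = 0.0302 and 0.0464). In diestrus too, Ccl3 lay below the median of each array, and Iigp1 did so on diestrus 1 and 2. The interferon response list as a whole had 12 higher and 13 lower means, 1 gene over the list alone and a camera adjusted p of 0.358. The immunoglobulin and B lineage list, with Jchain past the threshold and 2 genes over the list alone, had a median of 0.10, or 0.03 without immature 3 (camera adjusted p = 0.0109, and adjusted p = 0.363 with an estimated correlation), and its call ended without diestrus 1 (adjusted p = 0.0573). Uterine gland markers had 2 rising members among 12, Wfdc18 and Cxcl15 (0.81 ± 0.14, adjusted p = 0.0356), with a median of 0.18 (camera adjusted p = 0.000672, and adjusted p = 0.3 with an estimated correlation). Without diestrus 3, where muscle and homeobox values were high, that median was 0.05. The immature values of Cxcl15, at most 7.20, lay below the lower quartile of each array and were not shown to be above background. Its diestrus values lay below the median of each array.

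Single members of other lists also passed. Ptgs2, the inducible prostaglandin synthase gene, fell by 0.84 ± 0.16, Galnt3 by 0.43 ± 0.07 and Gclc, of glutathione synthesis, by 0.39 ± 0.06. Cyp1b1, which hydroxylates estrogens, rose by 0.56 ± 0.08, the matrix protease gene Mmp11 by 0.29 ± 0.06 and Btg2 by 0.42 ± 0.07 (adjusted p between 0.0206 and 0.0489 for these 6). Star, the cholesterol carrier of steroid-making cells, rose by 0.74 ± 0.14 (adjusted p = 0.0463), and its values on diestrus 2 and 3, the arrays with high Cyp11a1, were 9.21 and 9.12 against 8.72 on diestrus 1. In the circadian clock list 7 genes were higher and 3 lower over the list alone. Nr1d1 and Nr1d2 differed by 1.08 ± 0.33 and 0.57 ± 0.20 (adjusted p = 0.179 and 0.244), and the list's median was 0.17 (camera adjusted p = 0.012, and adjusted p = 0.563 with an estimated correlation). That call ended without immature 2 (adjusted p = 0.0638), and the median was 0.34 without immature 3 and 0.26 without diestrus 3. Esr1, Pgr and Pax8 differed by -0.01 ± 0.05, -0.13 ± 0.11 and -0.14 ± 0.10 (adjusted p at least 0.619). With the preset correlation 13 of 41 lists stood above and 8 below other genes, none did with an estimated correlation, and fry called 5.

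**Figure D2:**
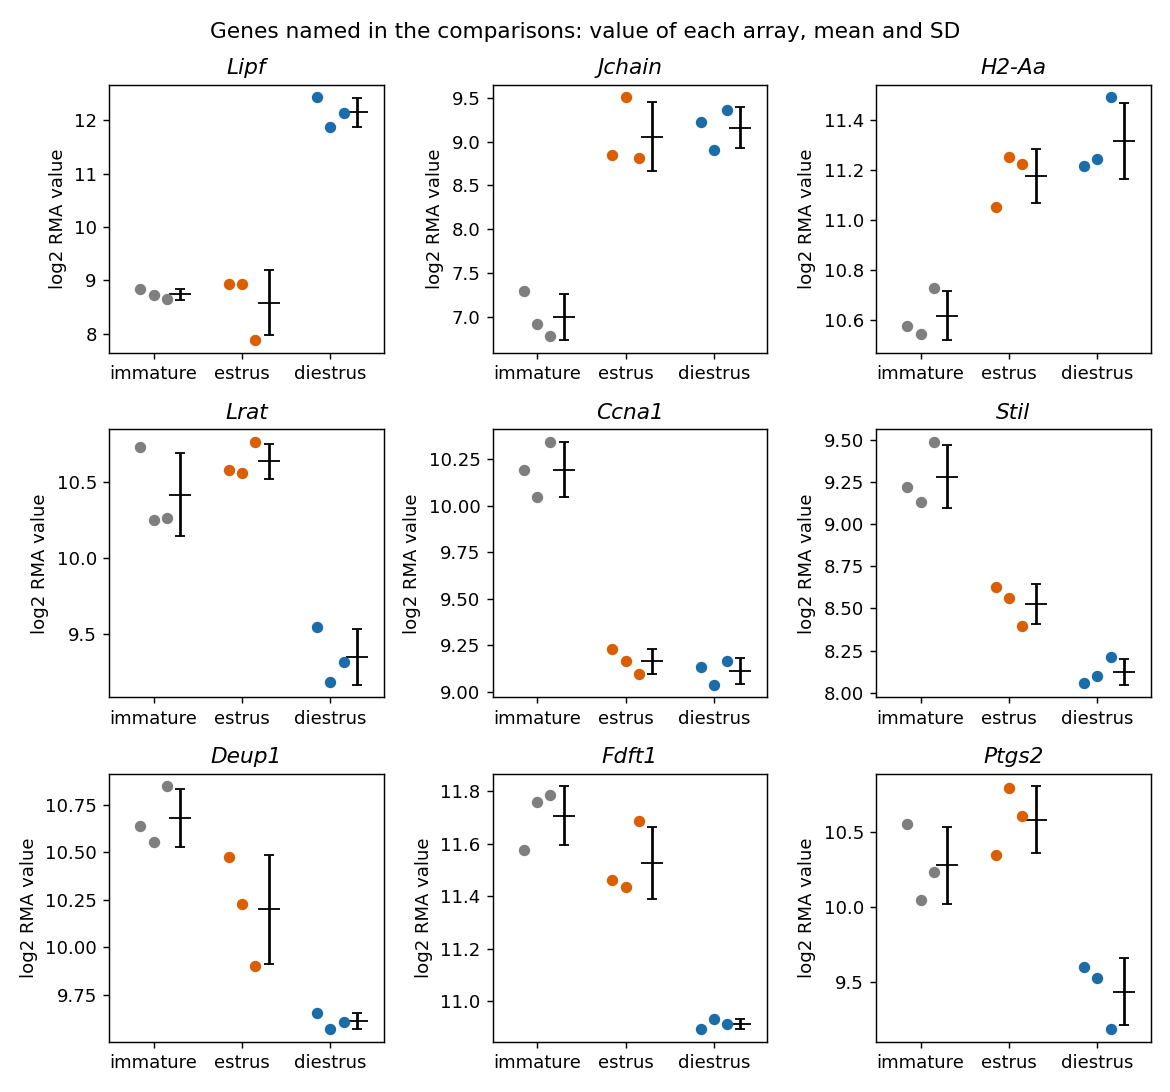
Log2 RMA value of 9 named genes on each array (points, 3 per group) with group mean and SD (bars beside the points). Lipf lies between 11.88 and 12.43 on the 3 diestrus arrays and at most 8.93 on the others, while Jchain is at most 7.30 on immature arrays and at least 8.81 on the mature ones.

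The comparison of diestrus with estrus addressed differences within the cycle of mature females. Lipf rose 11.9-fold in intensity, from 8.58 ± 0.61 to 12.15 ± 0.28 (SD, n = 3 each), a log2 difference of 3.57 ± 0.26 (SE; limma adjusted p = 0.00328). Its estrus values, at most 8.93, were not shown to be above background either. Abca1, a cholesterol exporter gene, rose by 0.92 ± 0.12, the metalloprotease gene Adam28 by 0.78 ± 0.12 and Mfge8, whose product marks dying cells for uptake, by 0.77 ± 0.08. Ccn2 (connective tissue growth factor) rose by 0.63 ± 0.06, Adamdec1 by 0.61 ± 0.07, Klhl24 by 0.60 ± 0.08 and Pik3cg by 0.59 ± 0.08. Lrat fell by 1.29 ± 0.14 and Ptgs2 by 1.14 ± 0.16, the kinase gene Pak3 by 0.97 ± 0.14, Rasd1 by 0.96 ± 0.12, Hsph1 by 0.81 ± 0.12, Ppp2r2c by 0.76 ± 0.09, the stress gene Gadd45a by 0.73 ± 0.09 and Olfm2 by 0.72 ± 0.07. Adjusted p lay between 0.0135 and 0.0452 for these 15 genes after Lipf. The estrus values of Adamdec1 and the diestrus values of Pak3 lay below the median of each array and were not shown to be above background. Among list members, Fdft1 fell by 0.62 ± 0.08 and Gclc by 0.48 ± 0.06, while Cyp1b1 and Mmp11 rose by 0.57 ± 0.08 and 0.41 ± 0.06 (adjusted p between 0.0229 and 0.0344).

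Between the stages 19 probe sets were higher and 26 lower in diestrus at an adjusted p under 0.05, 42 of them with 1 gene symbol. Lipf, Lrat and Ptgs2 were the 3 that differed at least 2-fold, and 2631 probe sets had an unadjusted p under 0.05. The calls rested on the spread shared with the immature arrays: limma on the 6 arrays of these groups alone called 0 probe sets, where the lowest adjusted p was 0.076, for Lipf and Lrat. The 45 calls became 53, 8 and 8 without immature 1, 2 and 3, then 1, 17 and 1 without estrus 1, 2 and 3, and 17, 1 and 105 without diestrus 1, 2 and 3. Of the 20 named genes past the threshold, Lipf alone was called in each of the 9 settings with 1 array left out. The number called was 19, 5 and 5 without immature 1, 2 and 3, then 1, 10 and 1 without estrus 1, 2 and 3, and 7, 1 and 17 without diestrus 1, 2 and 3. Array weights gave 3331 calls, and normalization again by quantiles or by loess moved the split to 32 higher and 27 lower or 32 higher and 28 lower.

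Heat shock and unfolded protein genes, a list written to check handling, had lower values in diestrus than in estrus. A difference in handling or time of day between the groups was not tested apart from stage. Of 22 measured, 21 had lower means in diestrus, Hsph1 passed the threshold and 14 were lower over the list alone (median -0.33; camera adjusted p = 7.39e-15, and adjusted p = 0.204 with an estimated correlation). The abundant chaperones Hspa8 and Hspa5 differed by -0.19 ± 0.06 and -0.36 ± 0.08 (adjusted p = 0.246 and 0.147). In cholesterol synthesis 18 of 20 means were lower, 1 gene fell and 9 were lower over the list alone (median -0.20; camera adjusted p = 8.09e-08, and adjusted p = 0.353 with an estimated correlation). In the multiciliogenesis program 17 of 20 means were lower, with 8 over the list alone (median -0.14; camera adjusted p = 4.63e-07, and adjusted p = 0.277 with an estimated correlation). Complement and antimicrobial genes had higher means in 26 of 31 cases, none past the threshold or over the list alone (median 0.18; camera adjusted p = 2.44e-08, and adjusted p = 0.112 with an estimated correlation; fry adjusted p = 0.0172). That median was 0.10 without estrus 1 and 0.11 without diestrus 2 or diestrus 3. Its member Lyz2, the lysozyme gene of macrophages, differed by 0.64 ± 0.16 (adjusted p = 0.197). Interferon response genes had higher means in 23 of 25 cases, 3 over the list alone (median 0.14; camera adjusted p = 5.01e-08, and adjusted p = 0.204 with an estimated correlation). This list stood below other genes in estrus against immature oviduct (median -0.12) and was not called in diestrus against immature oviduct. Secretory genes had higher means in 16 of 19, with 5 higher and 1 lower over the list alone (median 0.19; camera adjusted p = 2.24e-05, and adjusted p = 0.14 with an estimated correlation).

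Several lists followed diestrus 3. Smooth muscle genes had a median of 0.24 and extracellular matrix genes of 0.20 (camera adjusted p = 6.95e-05 and 6.63e-05, and adjusted p = 0.563 and 0.613 with an estimated correlation), with 2 and 0 genes higher over the list alone. Without diestrus 3 the medians became 0.01 and -0.02 and both calls ended (adjusted p = 0.539 and 0.931). The median of the matrix list was 0.14 without estrus 2 and 0.33 without diestrus 1. Acta2, smooth muscle actin, differed by 0.04 ± 0.15. Proliferation genes had a median of 0.08 (camera adjusted p = 0.031, and adjusted p = 0.767 with an estimated correlation), and without diestrus 3 it turned to -0.08. It was 0.16 without estrus 1, and 0.18 and 0.11 without diestrus 1 and 2. Without estrus 2 or estrus 3 that call ended (adjusted p = 0.656 and 0.0791). The ovarian list had a median of 0.18, 3 genes higher over the list alone and a camera adjusted p of 0.000431 (adjusted p = 0.538 with an estimated correlation), beside the high Cyp11a1 of diestrus 2 and 3. Its median was 0.33 without diestrus 1 and 0.27 without diestrus 3. Cyp26a1, which degrades retinoic acid, differed by -0.83 ± 0.16, Nr1d1 by 1.12 ± 0.33 and Nr1d2 by 0.45 ± 0.20 (adjusted p = 0.091, 0.261 and 0.515). The receptors and cell markers examined whatever their result did not pass: Pgr differed by -0.30 ± 0.11, Esr1 by -0.08 ± 0.05, Ltf by 0.34 ± 0.18, Foxj1 by -0.13 ± 0.13, Pax8 by -0.15 ± 0.10 and Mki67 by 0.24 ± 0.24 (adjusted p at least 0.398). Over the 41 lists, 20 stood above and 4 below other genes with the preset correlation, none with an estimated one, and fry called 1.

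**Figure D3:**
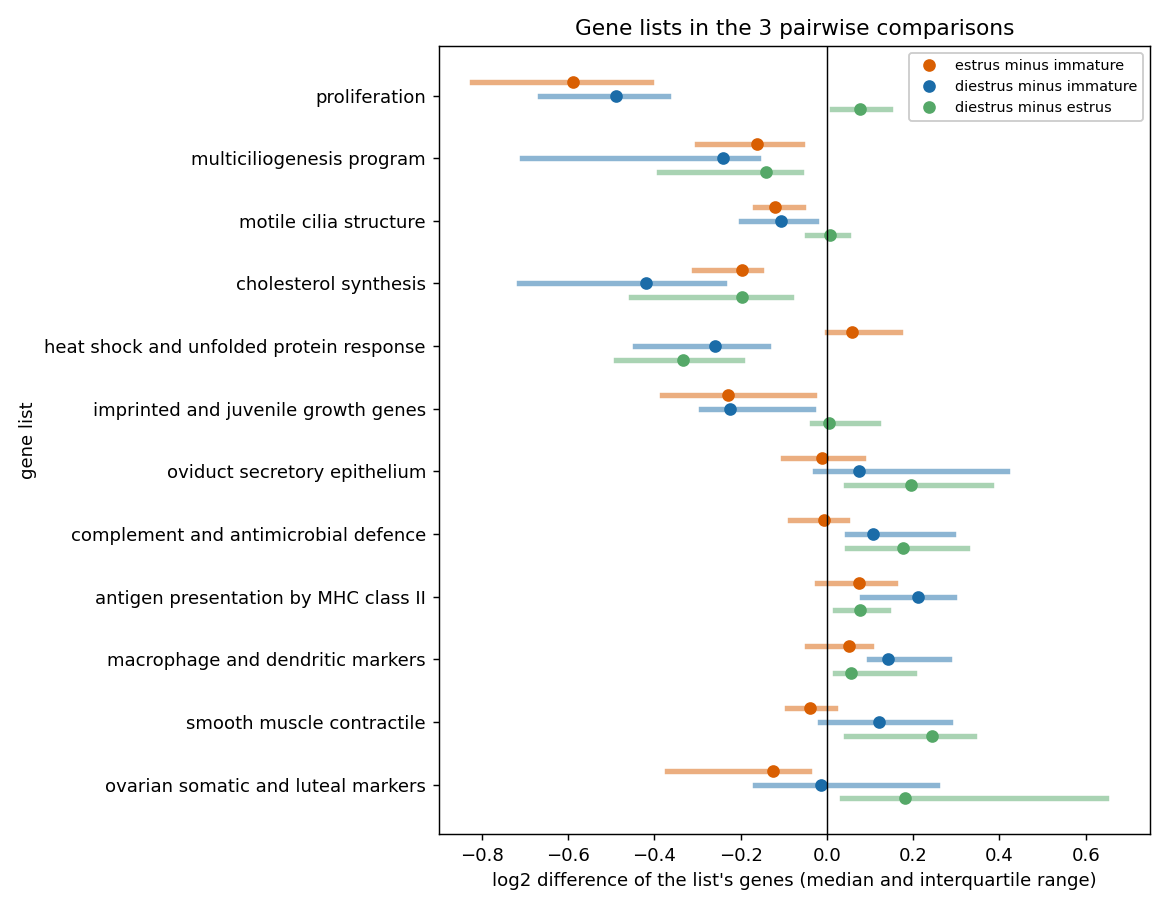
Median (points) and interquartile range (bars) of the log2 differences of the genes of 12 lists, 1 row per list, in the 3 pairwise comparisons. Proliferation genes lie below 0 in both comparisons with immature oviduct (medians -0.59 and -0.49), and heat shock genes lie below 0 in diestrus against either group (medians -0.26 and -0.33).

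Both mature stages were then set against immature oviduct together. Of the probe sets called in each comparison with immature arrays, 7 were higher in both stages and 12 lower in both, and 0 were called in opposite directions. Jchain was among the first, and Ccna1 and Stil were among the second. Lists independent of each other would share 0.03 and 0.11. These figures take no account of the immature arrays that the comparisons share. Simulations of unchanged groups set against the same immature arrays made almost no calls, so they gave no measure for the overlap. Across probe sets, which are not independent replicates, the 2 sets of differences correlated at 0.57, and with unchanged groups the simulated value averaged 0.48 and reached 0.57 or more in 32 of 100 draws. Their covariance was 0.0121 against a simulated mean of 0.00552, with 2 of 100 draws as high. The 3 immature arrays are too few to be split with at least 2 in each part, so the part of the overlap due to these arrays was not estimated from the data. The mean of both stages minus immature called 34 probe sets higher and 88 lower, and 16 of the 122 differed at least 2-fold. That count became 37, 14 and 25 without immature 1, 2 and 3, then 98, 53 and 49 without estrus 1, 2 and 3, and 47, 55 and 300 without diestrus 1, 2 and 3. The 19 shared calls became 5, 2 and 1 without immature 1, 2 and 3, 6, 3 and 4 without estrus 1, 2 and 3, and 4, 5 and 84 without diestrus 1, 2 and 3. A setting chosen after seeing the data left out immature 2 and diestrus 2. It called 2 probe sets for estrus, 10 for diestrus and 0 between the stages. Of the 8, 41 and 20 named genes, 1, 3 and 0 stayed called. With diestrus 3 left out as well, diestrus 1 alone stands for its group, so counts of calls are not given.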

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

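In this part, the counts of other splits and the test with the spread of each array's values were chosen before the result was seen, and the tests on immature 2, stomach, luteal and Hox transcripts and the stage label of diestrus 3 only after it was seen.

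Between the mature stages, 8 genes named in both comparisons of diestrus differed in their effect against immature oviduct, tested as diestrus minus estrus. The 8 were picked by their calls in that comparison, so these are the differences already reported there and not a further test. Lipf differed by 3.57 and Cyp1b1 and Mmp11 by 0.57 and 0.41. Lrat differed by -1.29, Ptgs2 by -1.14, Hsph1 by -0.81, Fdft1 by -0.62 and Gclc by -0.48. When limma was fitted to the 6 arrays of both stages alone, none of the 8 was called (2631 probe sets had an unadjusted p under 0.05 in the fit of 9 arrays).

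For each pair of groups, 10 splits of 6 arrays are too few for a share under 0.05. The real split was 1 of 10 with as many calls in each comparison: 24 calls for estrus minus immature against at most 0 in another split, 282 for diestrus minus immature against at most 1, and 45 for diestrus minus estrus against at most 1. For mature against immature, fitted as 2 groups, the real split gave 73 calls and 2 of 84 splits, the real one included, gave as many. This share lies under 0.05, but the arrays form 3 groups rather than 2, so the count alone does not exclude chance. The highest other split, diestrus against the other 6 arrays, gave 154, which points to a structure of the samples that follows diestrus.

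The first pattern is the lower level of 59 cell division and multiciliogenesis genes in mature oviduct: all 59 differences were negative, with a median of -0.44 and quartiles of -0.73 and -0.23. Ovarian tissue in the pool of immature 2, where Inha was highest, was tested by leaving that array out: the median was -0.42 and 58 genes stayed negative, which argues against it. A different spread of values between arrays was tested as a covariate: the median was -0.49 with 58 negative, which argues against it too. A lower share of dividing cells after day 21 may account for the pattern, as a hypothesis that these arrays of whole tissue did not test.

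The second pattern is Lipf, whose lowest diestrus value, 11.88, lay 2.94 above the highest other value. Stomach tissue in the diestrus pools was tested with 11 abundant stomach transcripts: their median difference between diestrus and estrus was 0.0017, and 0 were called, which argues against it. Luteal tissue was tested within diestrus: Lipf differed by -0.56 in the array with the highest luteal median than in the array with the lowest, while these medians differed by 1.37, which argues against it. Regulation of Lipf by stage may remain, as a hypothesis found on these data and not tested.

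The third pattern is diestrus 3, with Myh11 at 12.33, Des at 11.88 and Sprr2f, a gene of uterine epithelium, at 10.28 (7.16 to 8.32 elsewhere). A wrong stage label was tested on probe sets called without that array, placing it between the other group (0) and the other diestrus arrays (1). Its median position was 0.506 on 533 probe sets of diestrus minus immature (quartiles 0.258 and 0.854) and 0.638 on 105 of diestrus minus estrus (0.225 and 0.955). These probe sets were picked on the same arrays that set the scale, which can place a rightly labelled array below 1. The positions therefore cannot decide about the label. Lipf, called without that array too, stood at 12.13 on it. On the first principal component, computed with all arrays, diestrus 3 scored 13.6. The other diestrus arrays scored 13.2 and 14.3, and estrus and immature arrays at most 2.65. These scores argue against a pool wholly of estrus or immature oviduct, while a pool of mixed stage stays open. More tissue from the uterine end of the tube may be a source: the median of 6 posterior Hox genes lay 0.33 above the highest of the other 8 arrays, less than the 0.5 set for that source and outside the range set against it. Of these genes, 4 stood above all other arrays, Hoxd10 by 1.20. The 2 that did not, Hoxc10 and Hoxc11, had the lowest values of the 6 on diestrus 3 (7.74 and 6.57). They were not shown to be above background, so this source cannot be told apart from other causes. No biological explanation was tested for this array.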

How the results depend on the processing

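The settings that leave out immature 2 and diestrus 2, or these and diestrus 3, were chosen only after the result was seen. The values are calls for estrus minus immature, diestrus minus immature, diestrus minus estrus, mature minus immature and shared by both stages, with 24, 282, 45, 122 and 19 as reported.

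With 1 array left out the calls ranged from 1 to 95, from 41 to 533, from 1 to 105, from 14 to 300 and from 1 to 84. The highest of each came without diestrus 3. Array weights (0.325 for estrus 2 to 8.16 for estrus 3) gave 1023, 1288, 3331, 578 and 287. At least 2-fold left 7, 28, 3, 16 and 7, and an adjusted p under 0.01 left 2, 31, 1, 16 and 2, both by construction. Only the arrays of the groups compared gave 23 for estrus minus immature, 10 of them among the 24, with 3 of 8 named genes still called, 85 for diestrus minus immature, 0 for diestrus minus estrus and 9 shared, with fewer arrays to estimate the spread. Cyclic loess gave 5 for estrus minus immature and 5 shared. The low-intensity filter gave 131 for diestrus minus estrus, and probe sets with 1 symbol gave 12 for estrus minus immature, 91 for diestrus minus estrus and 7 shared, with fewer probe sets tested. Without immature 2 and diestrus 2 the calls were 2, 10, 0, 9 and 2. Without these and diestrus 3, diestrus 1 alone stands for its group, so counts are not given. Apart from the settings whose construction is named, the cause was not tested.

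With the replicate number as a block the calls were 4, 121, 13, 44 and 3. The numbers were not found to pair the arrays: 4 of 9 arrays correlated best with an array of their own number, and correlations within a number ran from -0.29 to 0.17, 3 of 9 over 0.1. Between different numbers the correlations ran from -0.26 to 0.29, 3 of 18 over 0.1.

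Over all settings, called genes stayed called in 756 cases and lost the call in 623, and genes not called gained one in 34 and moved by more than their error in 38, with 0 reversed. Called lists stayed called in 1173 cases and lost the call in 333, and lists not called gained one in 52 and moved by more than their error in 116. The proliferation list in diestrus minus estrus reversed from a median of 0.08 to -0.0777 without diestrus 3 (range with 1 array left out, -0.0777 to 0.183). Its median was -0.12 without immature 2, diestrus 2 and diestrus 3, where diestrus 1 alone stands for its group. The totals above include that setting. The cause was not tested. Calls of small differences are limited by the spread between 3 pools per group.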

Other observations

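The groups of probe sets in this part, and the test on haemoglobin, were chosen only after the result was seen. No test of a set was run on these groups.

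Immunoglobulin probe sets were picked by the start of their gene symbols, which can also take in a gene of another kind. All 32 had higher means in estrus than in immature oviduct (4 called, median 0.53, up to 2.09) and all 32 in diestrus (12 called, median 0.55, up to 2.47), while 0 were called between the stages (median 0.12). Only 16 of the 32 carried 1 gene symbol, so the 32 cannot be counted as separate genes. The planned immunoglobulin and B lineage list had medians of 0.06 and 0.10 in the same comparisons. Of 10 markers of B and plasma cells chosen later, 9 were measured, with medians of 0.01 in estrus and -0.01 in diestrus and 0 called. Blood left in the mature pools may be considered as a source of immunoglobulin transcripts, and the haemoglobin probe sets did not decide it. The prediction written for this test counted a median below 0 against blood. The median of 8 was -0.33 in mature minus immature, which meets it, with 4 called lower, 0 called higher and 3 positive differences. The outcome was left undecided because the verdict asked for all 8 differences to have the same sign. The median per array went the other way, from 8.18 to 8.24 on immature and 8.22 to 8.35 on mature arrays, while the 3 most abundant probe sets (means 11.98 to 12.94) differed by -0.62 to -0.76 and the other 5 had means of 6.23 to 8.32. The haemoglobin RNA of blood may also differ with age, which was not measured.

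Of 46 probe sets annotated to histone clusters, 37 had lower means in estrus (2 called, median -0.21, lowest -1.87) and 43 in diestrus (5 called, median -0.26, lowest -2.59), and 0 were called between the stages (median -0.03). Only 24 of the 46 carried 1 gene symbol. Of 7 fat cell markers 6 were measured, with medians of -0.33 in estrus and -0.34 in diestrus against immature oviduct and 0 called. Their median was 9.04 and 8.67 on immature 1 and 2, and 8.38 on immature 3, within the 8.17 to 8.57 of the mature arrays. The planned adipocyte list had medians of -0.18 and -0.20 with 0 of 12 genes past the threshold or adjusted over the list alone (camera adjusted p = 0.00981 and 0.0149, and adjusted p = 0.507 and 0.538 with an estimated correlation). Without immature 1 they were -0.11 for both and both calls ended (adjusted p = 0.0964 and 0.0934), without immature 3 the second was -0.31, and without estrus 2 the first call ended (adjusted p = 0.162). Xist stood at 12.71, 12.72 and 12.85 in immature, estrus and diestrus oviduct.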
